A study of Mus musculus with 4 samples.

How the data were processed

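RNA was measured on 4 Affymetrix arrays from sorted mammary basal cells of mice carrying the MMTV-Wnt1 transgene, 2 from animals on a casein (CAS) diet and 2 from animals on a soy protein isolate (SPI) diet. Per the labels' protocols, total RNA was taken from freshly sorted cells with a kit for small samples, and biotin-labelled copies were made from it for hybridization. GCOS and RMA are named in the submitters' processing notes, with their versions not given in the sources used here. The deposited values are log2 expression values by RMA, the base being taken from that method. The median of the 4 values of every probe set was 0 to within 5e-07, so the deposited log2 values had also been centred per probe set, a step that no label records. Centring removes the level of each gene and leaves only differences between arrays. No genome build is named, so no coordinates are given.

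The table held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 had exactly 1 gene in the platform annotation, 932 had several and 9160 were not listed there. Symbols were brought up to date through gene IDs with a table of the GRCm38.p6 assembly, which matched 34754 of 34958 annotated probe sets with 1 gene. This gave 18193 genes. The digits of the deposited values still carry the step size of the numbers before centring, which places most probe sets in a coarse level class: 8 to 16, 4 to 8, 2 to 4 or under 2 on the log2 scale. The classes were checked on probe sets of known kind. All 6 actin and Gapdh control probe sets fell in the class 8 to 16, as did 76 of 96 ribosomal protein probe sets, against 1 of 44 for olfactory receptors. At level 4 or above were 92 of the 96, but also 9 of the 44 and 5 of 27 bacterial control probe sets, so that level does not establish expression. The class follows the finest step among the 4 arrays, so a strong fall in either diet can lower it. A gene's value was the mean of its probe sets in the highest class it reached, a choice that can therefore depend on the diet difference. The median of the log2 values over the non-control probe sets was -0.0096 and -0.0058 on the CAS arrays and 0.0092 and 0.0056 on the SPI arrays.

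Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, SPI minus CAS, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The gene-wise spread had 2 residual degrees of freedom and 3.05 prior degrees of freedom. The test, the alternatives, the rule for named genes and 36 gene lists were fixed before the data were examined. The lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, again with Benjamini-Hochberg adjustment. At a preset correlation its p-values rest on the number of genes, treated as nearly independent, and not on the number of arrays. With an estimated correlation camera uses the 2 residual degrees of freedom, so a lost call need not mean correlated genes. The cytokine, chemokine, receptor, NF-kappaB, interferon and MHC class II lists were chosen because the series title names cytokines and chemokines, so these 7 lists are not independent of the study. Intervals are 95% intervals of the limma fit, and the number of arrays limits their precision.

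The centring forced some departures from the plan. A variance trend over intensity could not be used, so the test ran without a trend, and a trend over the level class was added as an alternative. The rule of the brightest probe set per gene became the highest level class, and a filter at the median level became a filter at level 4. Quantile normalization was not run, because it needs levels. Named genes were the 12 largest changes per direction among genes past the threshold at level 4 or above whose SPI arrays both lay on one side of both CAS arrays, the 4 members of each list with the smallest p, and 11 markers of the sorted population with the transgene. Other genes that are named were chosen after their values were seen. Alternatives were the replicate number as a block, each array left out in turn, arrays centred on their median, the mean of all probe sets of a gene, a filter at level 4, every probe set on its own, an ordinary t statistic, other thresholds, an estimated inter-gene correlation, fry in place of camera (a test of whether a list moves one way on balance, with no comparison to other genes), and immune markers taken out of the topic lists. Centring on the hybridization controls, which are bacterial and phage transcripts added before hybridization, was added after the data were seen.

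The fit was tested on simulated data with the spread of these arrays, 18193 genes and 200 changed genes in each of 5 runs. Of genes changed by 0.585 on the log2 scale 32% were recovered, of those changed by 1 90.4%, and of those changed by 2 99.2%. Of all calls in the simulations 6.26% were false. All 5 lists shifted by 0.3 were called, and 0 of 175 lists with no shift were called by camera. The simulated genes were drawn independently and the lists at random, so those lists held no inter-gene correlation by design. Real lists can hold more, as the milk protein list did (estimated correlation 0.643). The simulation therefore does not test camera on correlated lists.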

Results

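Gene expression was measured in freshly sorted basal cells of the mouse mammary gland, a population that holds stem cells, myoepithelial cells and myoepithelial progenitors per the labels. The mice carried MMTV-Wnt1, a transgene that expresses the Wnt1 ligand in the mammary gland. Of the 4 arrays, 2 came from mice on a control casein (CAS) diet and 2 from mice on a soy protein isolate (SPI) diet. The labels do not say that the arrays of a diet came from separate animals. The limma p-values therefore measure only the spread between these samples, which may be technical. The camera p-values at the preset correlation rest on the number of genes and are no measure of that spread. The comparison asks whether diet changed the transcripts of these cells, cytokine and chemokine genes above all, as the series title states. Values are log2 differences, since the deposited values hold no levels.

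The 5 largest falls on the SPI diet among the named genes were those of Glycam1, Wap, Tmprss11a, Lum and Crabp1. Glycam1, a mucin of milk, was 13.7-fold lower in SPI (95% interval 9.01 to 20.8, n = 2 arrays per diet, limma adjusted p = 0.00501). Wap, a whey protein, was 7.71-fold lower (5.54 to 10.7, adjusted p = 0.00518). Tmprss11a, a membrane serine protease, was 5.12-fold lower, and Crabp1, which binds retinoic acid, 4.86-fold lower. The small leucine-rich proteoglycans Lum and Fmod were 5.01-fold and 4.68-fold lower, Saa1, an acute-phase protein, 4.63-fold lower and Ifit1, an interferon-induced gene, 4.58-fold lower. Among the rises, Hal, which breaks down histidine, was 3.86-fold higher (3.06 to 4.87, adjusted p = 0.00609) and Egfl6, a secreted protein with EGF repeats, 3.36-fold higher. The mean of the 3 Ang probe sets was higher by 1.99 on the log2 scale (adjusted p = 0.00286), but they disagreed. The pair that can bind related transcripts was at 3.35 and 2.35, and the other probe set, at 0.285, did not pass (adjusted p = 0.221).

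Of 18193 genes, 674 (3.7%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 146 higher and 528 lower in SPI. Of the 175 that also differed at least 2-fold, 166 were lower. The others of the 12 largest falls by the naming rule were Cpxm1 (-2.16 on the log2 scale), Ms4a4d (-2.16), Ogn (-2.13) and Iigp1 (-1.97). The others of the 12 largest rises were Psd2 (1.40), Tmem88b (1.14), Kcnmb2 (1.12), Slc14a1 (1.09, from probe sets at 1.39 and 0.78, of which the latter did not pass on its own), Pcp4 (1.07), Arsj (1.04), Slc15a2 (0.99), Tg (0.95) and Hmgcll1 (0.92). Both SPI arrays lay on one side of both CAS arrays in 51.8% of genes, where chance gives 33.3%. By the weaker criterion of an unadjusted p under 0.05 with at least a 1.5-fold difference, 576 genes were found, 77 higher and 499 lower, and 3823 genes had an unadjusted p under 0.05 where 910 are expected with no effect. The count of 674 did not hold without CAS replicate 1, CAS replicate 2, SPI replicate 1 or SPI replicate 2, where a lone array stands for a diet. All 674 genes kept their direction there. Passing the threshold on all 4 arrays had already fixed that outcome, so it is no further support. Hybridization controls were lower in SPI by -0.17, and with arrays centred on them, which moved the median of all genes to 0.19, 2806 genes passed, 2276 higher and 530 lower, and the weaker criterion gave 572, 258 higher and 314 lower. Among genes at level 4 or above 1091 passed, 352 higher and 739 lower, and by an ordinary t statistic 0 passed, with 2900 at an unadjusted p under 0.05.

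**Figure D1:**
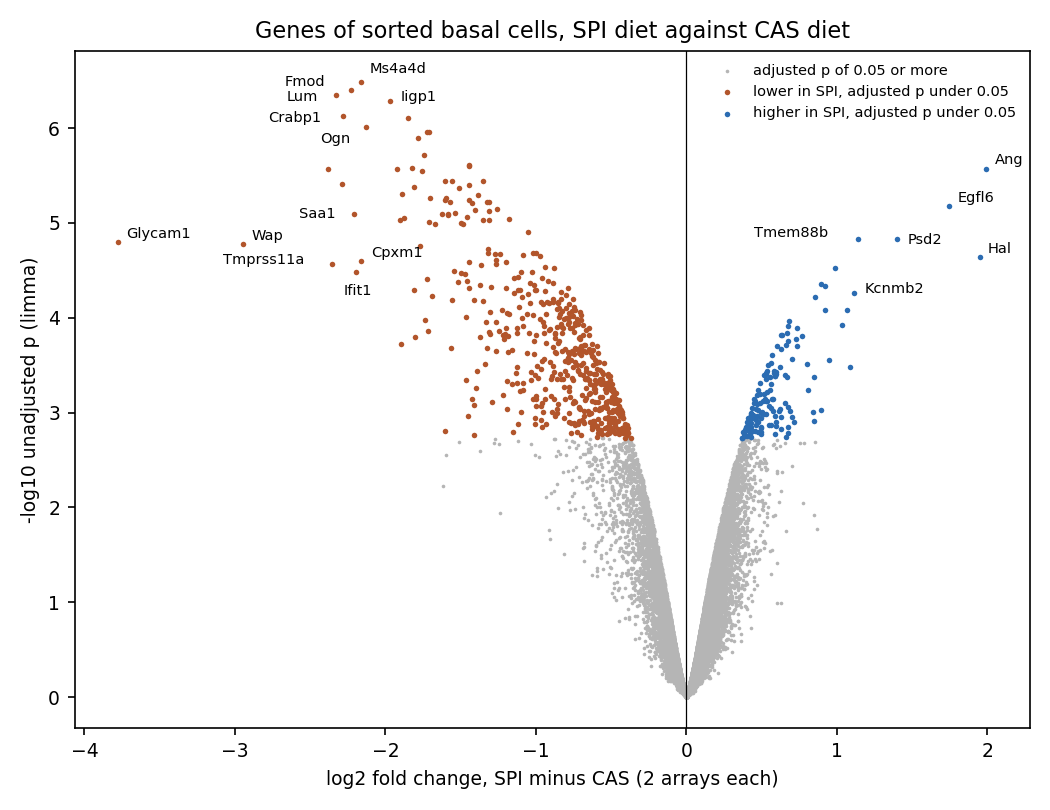
Each point is 1 of the 18193 genes, with its log2 fold change (SPI minus CAS, 2 arrays each) on the x axis and the negative log10 of its unadjusted limma p on the y axis, and colours mark the 146 genes higher and 528 genes lower in SPI at an adjusted p under 0.05. The falls reach -3.78 in Glycam1, while the rises end at 1.99 in Ang, a mean of 3 probe sets that range from 0.285 to 3.35.

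Of 35 chemokine ligand genes 9 fell in SPI and 26 did not pass the test. Ccl11, which attracts eosinophils, was 2.77-fold lower (2.29 to 3.35, n = 2 arrays per diet, limma adjusted p = 0.00734), Cxcl10, induced by interferon, 2.73-fold lower (2.44 to 3.04, adjusted p = 0.00286), Ccl5 2.58-fold lower and Cxcl13, which attracts B cells, 2.02-fold lower. A Cxcl13 probe set in a lower level class, not used for that value, was at -2.84 on the log2 scale (limma adjusted p = 0.00416). Its class may be lower because of that fall. Over all genes tested 0 of the list rose, and 15 fell and 3 rose when adjusted over the list alone. The median of the list was -0.09, and 0.07 with arrays centred on the hybridization controls, and the list lay below the other genes by camera (adjusted p = 7.02e-04). With an estimated correlation the call was lost (adjusted p = 0.444 with an estimated correlation). Without CAS replicate 1, CAS replicate 2 or SPI replicate 2 the median was -0.15, -0.050 or 0.0017, with camera adjusted p of 5.62e-04, 0.00846 and 0.00382. The list was taken from the series title and is not independent of the study. On the same arrays the fibroblast markers had a median of -1.26.

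Among the cytokines, Il6 was 2.30-fold lower in SPI (1.87 to 2.82, limma adjusted p = 0.0126), Tnf 2.15-fold lower (1.66 to 2.78, adjusted p = 0.0272), and Il1a and Csf3, the granulocyte growth factor, were lower by log2 differences of -0.56 and -0.53. Of 53 interleukins and other cytokines, 6 fell and 1 rose, and 11 fell and 5 rose when adjusted over the list alone. The 1 that rose was Il24, chosen after its value was seen (0.41 on the log2 scale). Camera placed the list below the other genes (adjusted p = 0.0179, and adjusted p = 0.462 with an estimated correlation), with a median of -0.06 that became 0.11 with arrays centred on the hybridization controls. The call was lost without CAS replicate 2 (adjusted p = 0.129, median -0.035), and the median was -0.091 without CAS replicate 1. By fry, which tests whether a list moves one way on balance and not against other genes, the adjusted p was 0.0904. Like the chemokines, these genes were listed because of the series title, and the fibroblast markers had a median of -1.26 on the same arrays.

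Of 36 inflammatory targets of NF-kappaB 9 fell in SPI and 27 did not pass the test. Beside Saa1, the matrix-degrading enzymes Mmp3 and Mmp13 were lower (-1.93 and -0.70 on the log2 scale) and Saa2 was 2.66-fold lower, though Saa2 was read only through a probe set that can bind related transcripts. None of the 36 rose over all genes tested, and 15 fell and 1 rose when adjusted over the list alone. The median was -0.15, and 0.019 with arrays centred on the hybridization controls, and camera placed the list below the other genes (adjusted p = 1.73e-06, and adjusted p = 0.243 with an estimated correlation). The list had been chosen from the series title. On the same arrays the fibroblast markers had a median of -1.26.

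Few receptor genes passed the test. Cxcr4, the receptor of Cxcl12, rose 1.59-fold (1.38 to 1.84, limma adjusted p = 0.0229), and it was the 1 of 21 chemokine receptors that passed, while 2 rose and 2 fell when adjusted over the list alone. Ccr7 (-0.65), Ackr1 (-0.45) and Ackr4 (0.35) did not pass. Of 55 cytokine receptors and signalling genes, Il17rb rose 1.48-fold (adjusted p = 0.0307) and Il18r1 fell by 0.78 on the log2 scale (adjusted p = 0.0362), and over the list alone 2 rose and 3 fell. Of 12 MHC class II genes 0 passed in limma, over all genes or adjusted over the list alone, with H2-Eb1 at 0.23, Ctss at 0.31, H2-DMa at 0.13 and Cd86 at 0.14 on the log2 scale. Camera gave an adjusted p of 0.917 for the chemokine receptors, 0.506 for the cytokine receptors and 0.665 for MHC class II, lists that also came from the title.

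Most of the interferon-response genes measured, which act against viruses and intracellular pathogens, fell in SPI. The GTPases Iigp1, Igtp and Gbp2 were 3.91-fold (3.50 to 4.36), 3.03-fold (2.66 to 3.46) and 2.85-fold (2.50 to 3.24) lower, and Oasl2 was 3.44-fold lower, with limma adjusted p between 0.00222 and 0.00309. Of 37 genes measured, 27 fell and 0 rose, and 31 fell when adjusted over the list alone. The median was -0.95, and the median of the list was 0.50 and 0.44 on the CAS arrays and -0.43 and -0.45 on the SPI arrays. Camera gave an adjusted p of 1.80e-27 (adjusted p = 0.212 with an estimated correlation). The estimated correlation was -0.0071, below the preset 0.01, so correlated genes do not explain that loss. The estimate leaves camera with the 2 residual degrees of freedom of the arrays. This list too was chosen from the series title. Macrophage markers, on the same arrays, had a median of 0.10 (0.073 to 0.18 without 1 array), and fibroblast markers one of -1.26.

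Most of the fibroblast markers fell in SPI, and some of the endothelial, pericyte and luminal markers did. Col1a1, the main chain of type I collagen, was 3.25-fold lower (2.79 to 3.79, n = 2 arrays per diet, limma adjusted p = 0.00321), Col3a1 2.94-fold lower (2.59 to 3.34) and Dpt, a matrix protein of the dermis, 3.37-fold lower. Of 32 fibroblast markers 26 fell and 0 rose, and 27 fell when adjusted over the list alone, with a median of -1.26. The other 6, Dcn among them at 0.0080, lay between -0.18 and 0.06. Camera gave an adjusted p of 2.27e-31 (adjusted p = 0.243 with an estimated correlation). Of 37 other genes of the extracellular matrix and basement membrane, 8 fell, including Fbln5 (2.04-fold), Timp3, Tnc and Sparcl1, and 14 fell and 3 rose when adjusted over the list alone. Its median was -0.12, and 0.045 with arrays centred on the hybridization controls, with a camera adjusted p of 2.00e-04 (adjusted p = 0.444 with an estimated correlation). Of 20 epithelial-mesenchymal transition regulators, 4 fell, the mesenchymal genes Fn1 (2.61-fold) and S100a4 and the epithelial genes Ocln and Esrp2, and 7 fell and 1 rose when adjusted over the list alone. That list had a median of -0.12, or 0.046 with arrays centred on the hybridization controls, and a camera adjusted p of 2.95e-04 (adjusted p = 0.301 with an estimated correlation).

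Of 29 endothelial and pericyte markers 9 fell and 0 rose, with 20 lower when adjusted over the list alone. The pericyte gene Rgs5 fell by 0.9974 on the log2 scale (SE 0.0786, limma adjusted p = 0.0087), and Cdh5 and Plvap, both of endothelial cells, were 1.92-fold and 1.81-fold lower. The median was -0.47, and -0.31 with arrays centred on the hybridization controls (camera adjusted p = 4.03e-14, and adjusted p = 0.243 with an estimated correlation). Pecam1, at -0.47, did not pass (adjusted p = 0.122). In the granulocyte and mast cell list, the mast cell proteases Mcpt4 (3.27-fold, 2.75 to 3.88, adjusted p = 0.00346), Cpa3 (2.98-fold) and Cma1 (-1.20 on the log2 scale) were lower. Of its 22 genes 5 fell and 0 rose, and 6 fell when adjusted over the list alone. Among the 5 is Ltf, which the milk protein list also holds. The median of this list was -0.13, or 0.035 with arrays centred on the hybridization controls, and camera gave an adjusted p of 2.03e-04 (adjusted p = 0.301 with an estimated correlation).

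Of 29 luminal markers, 10 fell and 0 rose, and 18 fell when adjusted over the list alone. They included Aldh1a3 (2.21-fold, from probe sets between -0.53 and -1.84 on the log2 scale), Ly6d (2.18-fold), the transcription factor Ehf (1.96-fold), Rab25 (1.72-fold) and the keratin Krt18 (1.66-fold, 1.43 to 1.92, limma adjusted p = 0.0198), while Krt8 (-0.36) and Epcam (-0.15) did not pass. The median was -0.49, and -0.32 with arrays centred on the hybridization controls (camera adjusted p = 7.10e-13, and adjusted p = 0.444 with an estimated correlation). Of 17 milk protein and lactation genes 6 fell, Glycam1, Wap, the iron-binding Ltf (-1.87 on the log2 scale) and the casein Csn1s1 (2.23-fold) among them, and 10 fell and 1 rose when adjusted over the list alone. That list had a median of -0.61 (camera adjusted p = 5.20e-08, and adjusted p = 0.491 with an estimated correlation). The median was -0.28 with the mean of all probe sets of a gene. The fry test, which makes no comparison with other genes, gave an adjusted p of 0.0904 for a move one way.

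**Figure D2:**
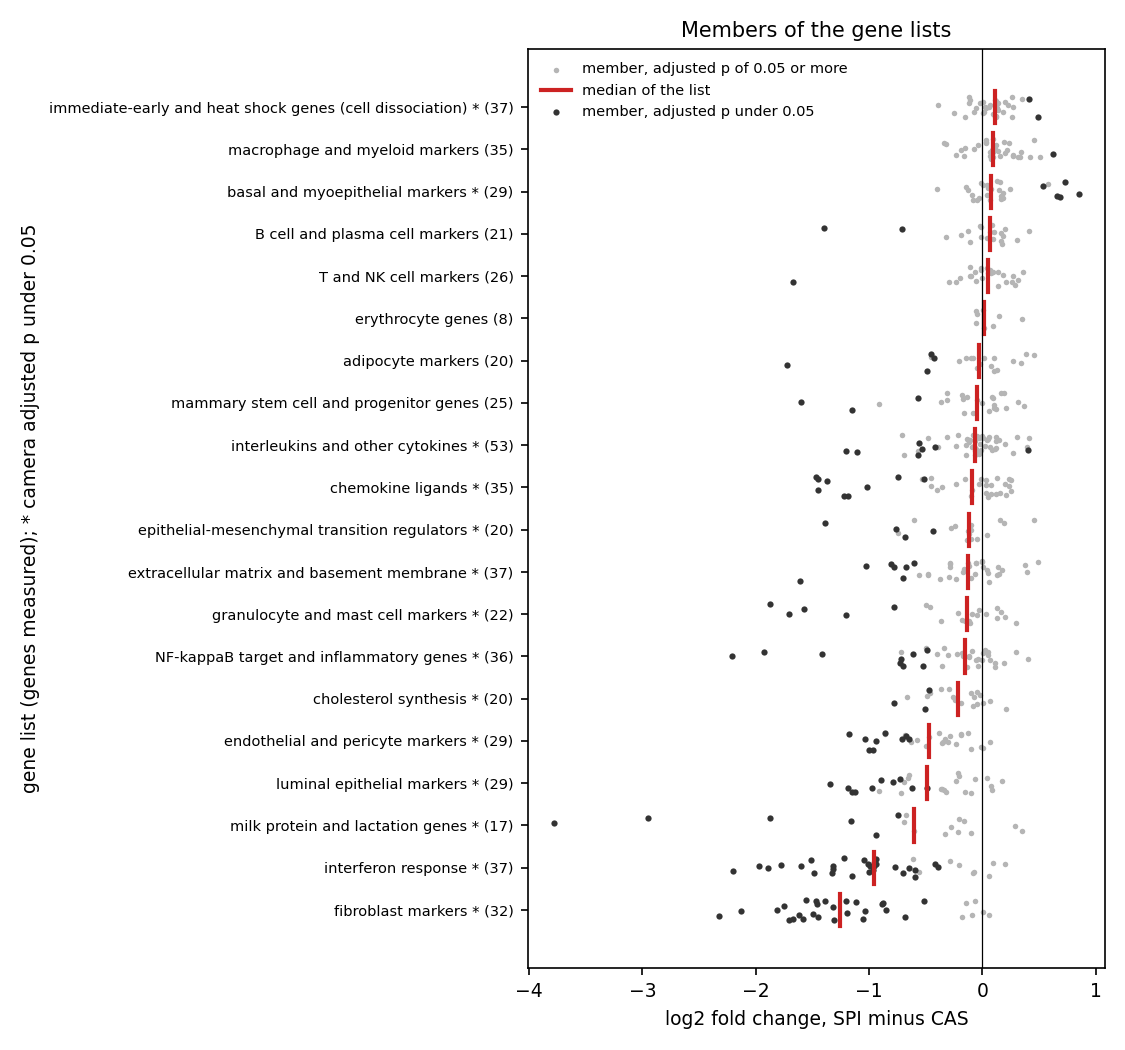
Points are the members of each gene list, with the log2 fold change (SPI minus CAS) on the x axis, dark points for members at an adjusted p under 0.05, red bars for list medians and asterisks for lists that camera called. The medians of the fibroblast (-1.26) and interferon (-0.95) lists lie furthest below 0, and those of the macrophage, basal and T cell lists lie within 0.10 of it.

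Of 29 basal and myoepithelial markers 5 rose in SPI and 24 did not pass the test. Krt15 was 1.66-fold higher in SPI (1.47 to 1.88, limma adjusted p = 0.0126), Oxtr, the oxytocin receptor, 1.61-fold higher and Vcan 1.58-fold higher. Trp63, the transcription factor of basal epithelium, was 1.45-fold higher (1.27 to 1.65, limma adjusted p = 0.0313). The Trp63 probe set used missed the threshold when every probe set was tested on its own (limma adjusted p = 0.0625). The other Trp63 probe sets, at 0.16, 0.23 and 0.41 on the log2 scale, did not pass. This limit is not particular to Trp63. Probe sets used for other genes named as passing missed it too, such as Il1a (0.0504), Csf3 (0.066), Il17rb (0.0598), Il18r1 (0.0624), Hes1 (0.0531) and Notch2 (0.0707). The abundant markers Krt5 (-0.04), Krt14 (0.15) and Acta2 (0.04, from a probe set that can bind related transcripts) did not pass, nor did the transgene's gene Wnt1 (-0.09). Of the 29 markers 0 fell, and 6 rose when adjusted over the list alone. On the same arrays the fibroblast markers had a median of -1.26 and the luminal markers one of -0.49. The median was 0.08, and 0.25 with arrays centred on the hybridization controls. Camera gave an adjusted p of 0.00636 (adjusted p = 0.462 with an estimated correlation), and the call was lost without CAS replicate 1 (adjusted p = 0.0579). Of 25 stem cell and progenitor genes, Nrp1 (3.04-fold), Aldh1a3 and Aldh1a1 fell and Axin2 (0.37) did not pass. Adjusted over the list alone 5 were lower and 2 higher. Camera did not call the list (adjusted p = 0.156), while fry, which makes no comparison with other genes, gave an adjusted p of 0.0431. With arrays centred on the hybridization controls camera placed this list below the other genes (adjusted p = 0.0263), at a median of 0.12 where that of all genes was 0.19. Without that centring its median was -0.04.

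**Figure D3:**
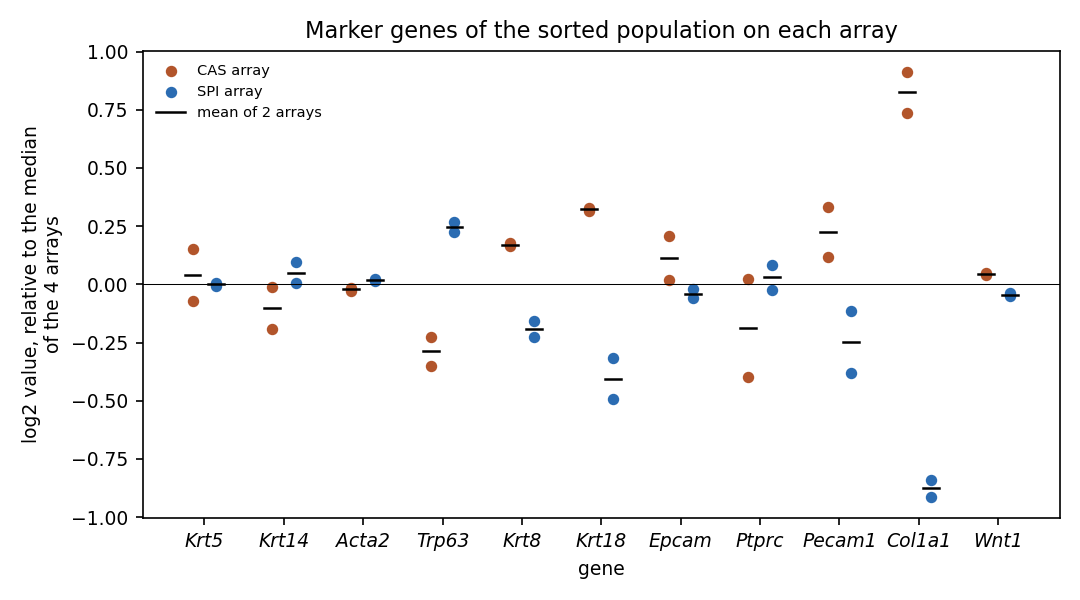
Values on each array of 11 marker genes of the sorted population, on the log2 scale relative to the median of the 4 arrays, with a bar at the mean of the 2 arrays of a diet. Col1a1 differs by -1.70 and Krt18 by -0.73 between the diets, while Krt5 and Acta2 differ by -0.04 and 0.04.

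Few immune cell markers passed the test. Of 35 macrophage and myeloid markers 1 rose, Ncf4 (1.55-fold, 1.29 to 1.85, limma adjusted p = 0.0444), and 0 passed when adjusted over the list alone, with C1qc at 0.42, Cd68 at 0.51 and Cd14 at -0.32. The list median was 0.10 and camera missed the threshold at an adjusted p of 0.0557 (adjusted p = 0.833 with an estimated correlation). Without CAS replicate 2 or SPI replicate 1 the median was 0.17 or 0.18 and camera placed the list above the other genes (adjusted p = 0.00213 and 0.00711). Of 26 T and NK cell markers 1 fell, Thy1 (3.18-fold), which fibroblasts also express, and of 21 B and plasma cell markers Jchain (2.63-fold) and Ighm fell. Ighm (1.63-fold) is the mean of probe sets at -1.41 and -0.0040 on the log2 scale, which can bind related transcripts. Adjusted over the list alone, 1 fell and 2 rose in the former and 3 fell and 2 rose in the latter. Ptprc, the pan-leukocyte gene, was at 0.22 and did not pass. Of 20 adipocyte markers Lpl (3.30-fold), Car3, Pnpla2 and Fabp4 fell (neither of the Fabp4 probe sets on its own), and 5 fell and 4 rose when adjusted over the list alone. Of 8 erythrocyte genes 0 passed in limma, over all genes or over the list alone. Camera called none of the T and NK, B and plasma, adipocyte and erythrocyte lists, with adjusted p of 0.747, 0.917, 0.428 and 0.768.

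Some Wnt, Notch and TGF-beta genes passed the test, in both directions, where 3.7% of all genes passed. Ccnd1, a cyclin and Wnt target, was 1.83-fold lower in SPI (1.57 to 2.14, limma adjusted p = 0.0138), Nkd2 1.55-fold lower and Sfrp2 1.35-fold lower, while Ccn4 was 1.37-fold higher. These were the 4 of 41 Wnt targets that passed, and 5 fell and 4 rose when adjusted over the list alone (camera adjusted p = 0.685). Of 33 Wnt ligands and receptors Wnt5b fell 1.42-fold, and over the list alone 2 fell and 1 rose (camera adjusted p = 0.682). Of 25 Notch genes, Notch3 (-0.97 on the log2 scale), Hes1 (1.52-fold) and Notch2 (1.40-fold) fell and Rbpj rose 1.34-fold. Notch3 was read through a probe set that can bind related transcripts, and the endothelial and pericyte list holds it too. Over the Notch list alone 3 fell and 2 rose (camera adjusted p = 0.917). Of 38 TGF-beta and BMP genes Ltbp1 fell by 1.0022 on the log2 scale and Bmpr1b rose 1.74-fold, with 2 lower and 3 higher when adjusted over the list alone (camera adjusted p = 0.719). Of 27 estrogen and progesterone response genes, Ccnd1 and the estrogen receptor Esr1 (1.54-fold) fell, the same number as over the list alone (camera adjusted p = 0.258).

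Of 20 sterol synthesis genes 3 fell in SPI and 17 did not pass the test. Stard4, a cholesterol carrier, was 1.72-fold lower in SPI (1.51 to 1.95, limma adjusted p = 0.0122). The enzymes Fdft1 and Dhcr7 were 1.42-fold and 1.38-fold lower, Fdft1 being read through a probe set that can bind related transcripts. When every probe set was tested on its own, those used for Fdft1 and Dhcr7 missed the threshold (limma adjusted p = 0.0647 and 0.0626). Of the list 0 rose, and 8 fell when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 2.64e-05, and adjusted p = 0.444 with an estimated correlation). The median was -0.049 with arrays centred on the hybridization controls and -0.14 without CAS replicate 1. On the same arrays the fibroblast markers had a median of -1.26 and the luminal markers one of -0.49. Of 27 fatty acid and triglyceride synthesis genes the desaturases Scd1 (1.93-fold) and Scd2 (1.68-fold) and the elongase Elovl7 fell and Acly rose 1.47-fold, with 7 lower and 6 higher when adjusted over the list alone (camera adjusted p = 0.506). Of 30 aryl hydrocarbon and NRF2 response genes Aldh3a1, Gsta4 and Cyp1b1 fell (-1.18, -1.02 and -0.46 on the log2 scale), and over the list alone 4 fell and 1 rose (camera adjusted p = 0.46).

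Of 37 immediate-early and heat shock genes, which respond to cell dissociation, 2 rose in SPI and 35 did not pass the test. Fosb was higher by 0.49 on the log2 scale (SE 0.0652, limma adjusted p = 0.0282) and Hspe1 1.33-fold higher. When every probe set was tested on its own, those of Fosb (limma adjusted p = 0.0612) and Hspe1 (0.1 and 0.0838) missed the threshold. In the list, 2 genes rose and 1 fell when adjusted over the list alone. The median was 0.12, and 0.28 with arrays centred on the hybridization controls (camera adjusted p = 0.0364, and adjusted p = 0.501 with an estimated correlation). That call was lost without CAS replicate 2, SPI replicate 1 or SPI replicate 2 (adjusted p = 0.134, 0.0504 and 0.0838), and with that centring (adjusted p = 0.0668). Few other genes of growth and stress passed, namely Birc5 (1.34-fold lower) of 49 cell cycle genes, P4ha2 (1.71-fold lower) of 27 glycolysis and hypoxia genes, Chac1 (1.39-fold higher) of 28 unfolded protein response genes and Trp53inp1 (0.51 on the log2 scale) of 24 p53 and apoptosis genes. Adjusted over the list alone, 0 cell cycle genes passed, 1 glycolysis and hypoxia gene fell and 2 rose, 1 unfolded protein response gene rose, and 1 p53 gene rose and 1 fell. Of 64 oxidative phosphorylation genes and 44 ribosomal protein genes 0 passed in limma, over all genes or over the list alone. Camera gave adjusted p of 0.685, 0.917, 0.0695, 0.917, 0.243 and 0.733 for these lists, in the order given. Oxidative phosphorylation was called lower without CAS replicate 1 (adjusted p = 0.00791) and the unfolded protein response higher without SPI replicate 1 (adjusted p = 0.0488).

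The control probe sets give a measure of RNA quality. The difference between the 3' and 5' probe sets changed between diets by 0.07 for actin and -0.02 for Gapdh on the log2 scale. The 18S rRNA controls were at 0.10 and 0.57 on the CAS arrays and at -0.10 and -0.40 on the SPI arrays, a difference of -0.59 that was not tested.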

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

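The tests of marker lists described here were chosen after the results they concern had been seen. Outside the genes of the report, 20 probe sets with no single gene in the annotation were higher in SPI at an adjusted p under 0.05 (limma, Benjamini-Hochberg), with log2 differences of 0.58 to 1.21. They were picked out because no comparison of the report uses them, and 49 such probe sets were lower.

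The falls of stromal, endothelial and luminal markers raise the question of cell composition. A lower share of basal cells in the CAS sorts, with every other cell type in proportion, is argued against, because the median of the macrophage markers lay above that of the endothelial markers by 0.48 (95% bootstrap interval over genes 0.36 to 0.82), with -0.37 and -0.22 on the CAS arrays and 0.20 and 0.35 on the SPI arrays. More luminal cells in the CAS sorts may account for part of it, but cannot be told apart from a change within cells. Of 30 further luminal genes in no fixed list, 28 were below 0 with a median of -0.46, which either would give. Of the 30, 29 are at level 4 or above in these sorts and some belong to other epithelia too. More fibroblasts in the CAS sorts cannot be told apart from a change within cells either. In a second fibroblast list of 33 genes, 14 fell and 0 rose (median -0.52), and in a list of 20 fibroblast genes that encode no matrix protein, 13 of them shared with it, 11 fell and 0 rose (median -0.71). Without the 9 of these 20 that fixed lists hold, the median was -0.52 with an interval of -0.94 to 0.18, and 4 of the 15 fibroblast markers in the highest level class, Dcn among them, lay between -0.20 and 0.20. A diet effect within basal cells stays open, untested.

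For the interferon genes, macrophages carried over into the CAS sorts are argued against, and T, NK and B cells less firmly. The 55 macrophage, T, NK and B cell markers had a median of 0.10 (bootstrap interval over genes 0.07 to 0.16, and 0.05 to 0.18 with 1 array of a diet alone). That interval rests on the number of genes and not on the arrays. On the arrays their medians were -0.12 and -0.0023 for CAS and 0.027 and 0.078 for SPI, so the CAS arrays also differed. Of the 55, 32 were macrophage markers, so the pooled median is mostly theirs. The T and NK list and the B and plasma cell list had medians of 0.05 and 0.07. They had only 14 and 10 genes at level 4 or above, a level that does not establish expression. Mast cells stay open, as the median of the granulocyte and mast cell markers was -0.13 (interval -0.46 to -0.03) with Mcpt4, Cpa3 and Cma1 lower, and so do plasma cells, not tested on their own, as Jchain fell. One array alone is argued against as well, since the smallest fall of the list's median without any 1 array was -0.88. Fibroblasts in the CAS sorts could also bring interferon transcripts, and cannot be told apart from a response within basal cells, because no list here tells which cells express these genes and the interferon median differed from the fibroblast median by 0.30 (interval -0.02 to 0.72). An effect of diet stays open.

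Only 3 splits of the 4 arrays into pairs exist, too few for a share under 0.05. The real split gave 674 genes, 1 of the 3 splits gave as many, and the highest of the others gave 0.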

How the results depend on the processing

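Centring on the hybridization controls and the trend over the level class were chosen after the data were seen, and the other alternatives before. Quantile normalization was not run, because the centred values hold no levels. The count of 674 changed genes was 364 with the replicate number as a block (34 higher and 330 lower, 340 of the 364 shared), 1091 at level 4 or above (fewer genes tested), 1473 at an adjusted p under 0.10, 1150 with a trend over the level class and 2806 with hybridization-control centring, and 0 by an ordinary t statistic (2900 at an unadjusted p under 0.05). Without 1 array it was 0 to 0 in limma, with 2492 to 3076 genes at an unadjusted p under 0.05, where 1 residual degree of freedom remains and the lone array is assumed to vary like the other pair. Median centring, the mean of all probe sets and every probe set on its own gave 711, 727 and 676. The count of 576 by the weaker criterion was 1136 over every probe set on its own, 186 at 2-fold or more, 532 to 656 without 1 array, and 572 with hybridization-control centring, which moved its split from 77 higher and 499 lower to 258 and 314. The 14 called lists were 13 to 15 without 1 array, 14 with the replicate block and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. The estimated correlation also leaves camera 2 degrees of freedom, so the drop to 0 does not come from correlated genes alone. By fry, which does not compare a list with other genes, 14 lists passed, 12 of them among the called ones. The milk protein and interleukin lists did not pass by fry (adjusted p = 0.0904 for both). The stem and progenitor list (0.0431) and the unfolded protein response (0.0381) passed by fry without being called by camera. Arrays of the same number did not deviate together (correlation over genes -0.08, with only 2 pairs), so the numbers were not taken as pairs. The block ended the call of the immediate-early list (adjusted p = 0.0619) and made one for the macrophage list, as did median centring (adjusted p = 0.0425) and the filter at level 4 (0.0326).

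Some values changed sign, and the cause was not tested except where a constant was added. Hybridization-control centring adds 0.17 to every gene, which turned 16 list medians positive: chemokine ligands 0.075, interleukins 0.11, cytokine receptors 0.14, NF-kappaB targets 0.019, Wnt ligands 0.16, stem and progenitor genes 0.12, granulocyte and mast cells 0.035, adipocytes 0.14, estrogen response 0.12, aryl hydrocarbon response 0.16, fatty acid synthesis 0.11, glycolysis 0.16, oxidative phosphorylation 0.13, ribosomal proteins 0.16, extracellular matrix 0.045 and transition regulators 0.046. Of these 6 were lists that camera called, and camera called all 6 again below the other genes, while the immediate-early list lost its call (adjusted p = 0.0668) and the stem and progenitor list gained one, also below them (0.0263). It also turned Epcam (0.014), Rpl35 (0.051), Wnt1 (0.081), Bpgm (0.11) and Krt5 (0.13), none of which had passed. The mean of all probe sets turned Epb42 to -0.019, Wnt ligands to 0.030, Notch to -0.021, erythrocyte genes to -0.0046, aryl hydrocarbon response to 0.017, glycolysis to 0.0050 and ribosomal proteins to 0.0027. Erythrocyte genes were at -0.0031 with median centring and -0.019 at level 4 or above. Without 1 array the list medians ranged from -0.15 to 0.0017 for chemokine ligands, the one called list among them, -0.017 to 0.089 for Notch, -0.0023 to 0.077 for T and NK cells, -0.050 to 0.054 for aryl hydrocarbon response, -0.0058 to 0.024 for glycolysis, -0.061 to 0.0077 for cytokine receptors, -0.026 to 0.028 for Wnt ligands, -0.061 to 0.023 for adipocytes, -0.039 to 0.070 for erythrocytes, -0.082 to 0.023 for oxidative phosphorylation, -0.034 to 0.072 for chemokine receptors and -0.049 to 0.0095 for fatty acid synthesis. The genes ranged from -0.15 to 0.070 for Krt5, -0.12 to 0.31 for Epb42 and -0.11 to 0.0011 for Bpgm. Of the 107 named genes that passed, 0 changed sign in limma under any alternative run on them. The block and the trend cannot change a sign, and leaving out 1 array cannot reverse genes picked for passing. Only the mean of all probe sets and the recentring of arrays could have done so. Of the 107, 78 passed again with the block, 94 with the mean of all probe sets and 97 with hybridization-control centring. Arrays give no depth, and signal over background cannot be read from centred values beyond the level class, which put 625 of the 674 genes at level 4 or above, and Oasl2, Mcpt4 and Jchain below it. Median and mean differed in sign for the Notch (0.03 and -0.03), T and NK cell (0.05 and -0.01), B cell (0.07 and -0.04), chemokine receptor (0.04 and -0.0015) and glycolysis (-0.0048 and 0.0056) lists, none of them called.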

Other observations

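Genes of squamous and suprabasal keratinocytes, and complement genes, were looked at after their members had been seen among the largest changes. In SPI the keratin Krt6a (-1.46 on the log2 scale), the cornified envelope genes Sprr1a (-1.45) and Scel (-1.53), the desmosomal cadherin Dsg1a (-1.06) and the protease Klk11 (-1.56) were lower, each past the threshold (limma, Benjamini-Hochberg). Of 56 squamous genes measured, 20 fell and 1, Hal, rose, and 24 fell and 1 rose when adjusted over the list alone. The other 35 did not pass, among them Krt1 (0.29), Krt10 (0.10), Ivl (0.11), Lor (0.04) and Flg (0.04). Of the 56 squamous genes, 40 lay below 0 and 16 above it. Among 22 complement genes 9 fell and 0 rose, and 10 fell and 5 rose when adjusted over the list alone. The falls include Serping1 (-1.85), C2 (-1.31) and Cd55 (-0.84), while C1qa (0.46) did not pass. Of the 22 genes 10 lay above 0 and the median was -0.02. On the same arrays fibroblast markers had a median of -1.26 and luminal markers one of -0.49. A test of the complement list would restate the observation that prompted it and is not used here.

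A lower squamous programme in SPI is a candidate explanation of the keratinocyte genes, tested after the result was seen on 44 list members that had not been noticed beforehand and are in no other list. Of these 10 fell and 0 rose, with a median of -0.11 that turns positive under hybridization-control centring, which adds 0.17 to every gene, and camera gave an adjusted p of 4.2e-05 over the 5 added lists. With an estimated correlation the adjusted p was 0.108, so it stays open. Of the luminal markers 10 of 29 fell on these arrays too, and of the fibroblast markers 26 of 32, and 28 of 30 further luminal genes were below 0 with a median of -0.46. The medians of the 44 genes were 0.014 and 0.087 on the CAS arrays and -0.032 and -0.038 on the SPI arrays.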
